A study of Mus musculus with 24 samples.

How the data were processed

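Total RNA from whole lung of C57BL/6 mice was measured on 24 one-colour Agilent arrays with Cy3 label, per the labels. The labels give 6 groups, formed by PBS or bleomycin combined with a control gapmer, gapmer 1 or gapmer 3, with 3 arrays in each PBS group and 5 in each bleomycin group. RNA integrity numbers, given in the labels, averaged between 9.03 and 9.68 per group. Dose, time after bleomycin, sex of the animals and array batch are not given in the sources used here.

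The deposited values are log2 intensities, quantile-normalised between arrays by the authors, as the values show: the medians of the 24 arrays lay between 6.485 and 6.495, and the largest SD of any quantile between arrays was 0.0158. Per the submitters' processing notes limma was used, without a version, and background correction and filters are not given in the sources used here. No genes had been centred. The table held 62976 array features, of which 31465 carried 1 gene symbol and 31511 none. Symbols were brought to the current names with an annotation table for GRCm38.p6, used for names only: of 20774 symbols 18550 were current, 2003 were updated by accession, 311 by synonym and 5 were kept. For the 6176 genes with more than 1 feature the one with the highest mean over all arrays was used, giving 20728 genes, with no filter on level.

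Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) in one fit of all 24 arrays with 6 group means, 18 residual degrees of freedom and 3.26 prior degrees of freedom. The median residual SD of a gene was 0.14 on the log2 scale. The contrasts were bleomycin against PBS under the control gapmer, each gapmer against control in bleomycin and in PBS mice, the difference in the bleomycin response with each gapmer, and gapmer 3 against gapmer 1 in bleomycin mice. A Benjamini-Hochberg adjusted p under 0.05 over all genes of a contrast was called. Tables were handled with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and plots were drawn with matplotlib 3.10.9.

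Gene lists for pathways, cell types and other tissues were written before the data were examined, as were the groups, contrasts, tests, naming rule and most alternatives. They hold 499 members, of which 476 were measured and 5 are on more than 1 list, and 31 lists had at least 3 measured members. The lists are extracellular matrix, TGF-beta response, contractile and myofibroblast, resident fibroblast, alveolar type 1 and type 2 cell, damage-associated epithelium, airway epithelium, endothelium, alveolar macrophage, monocyte-derived macrophage, neutrophil, T cell, NK and cytotoxic cell, B and plasma cell, cytokines and chemokines, proliferation, interferon response, p53 and DNA damage, antioxidant, Wnt signalling, described targets of the microRNAs in Dnm3os, cardiac muscle, skeletal muscle, red blood cell, adipose tissue, thymus, mesothelium, circadian clock, immediate early and sex-linked genes. Each was tested with fry from limma (directional p, adjusted over lists in a contrast), and with camera at a preset and at an estimated correlation as alternatives. Counts of list members were also adjusted over the list alone.

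The genes named are a fixed set (Dnm3os, Dnm3 and matrix, fibrosis, microRNA target and alveolar genes), the 10 with the largest rise and the 10 with the largest fall per contrast among called genes with no overlap between groups and a level above the median, and up to 4 called members per list. Where no gene was called, the 3 with the smallest p in each direction are given as values. A marker list for squamous epithelium and the set of 10 bleomycin-induced genes that lost most of their rise were chosen after values were seen.

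Every feature of Dnm3os, the extracellular matrix score and the bleomycin-response score were compared with two-sided exact permutation tests. The matrix score is the mean over members of the log2 value minus the PBS control mean. The bleomycin-response score is the mean of raised minus the mean of lowered genes, chosen in mice of the other gapmer. Changes with both gapmers were compared by correlation and covariance across genes, with 100 simulations of unchanged groups that share controls and with the controls split between the gapmers.

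The fit was tested on simulated data with changes of known size. It recovered between 56.9% and 82% of genes changed 1.5-fold, between 87.3% and 98.6% of those changed 2-fold and between 98.4% and 100% of those changed 4-fold, and the largest share of false calls was 6.6%. Alternatives were another quantile normalisation, median centring, leaving out dim genes, the mean of all features of a gene, every feature tested, a variance trend, robust variance, array weights, only the groups compared, the RNA integrity number as a covariate, the replicate number as a block, other list tests, other score averages and scales, and each array left out in turn. After seeing the data, removal of a position trend (block medians over 16 lines by 17 columns) and leaving out the 4 arrays with the strongest trend were added. Features without a gene symbol were left out of the main tests because they cannot be named, and coordinates were not used.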

Results

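Gene expression was measured in whole lung of C57BL/6 mice on 24 one-colour Agilent arrays, one per sample. Mice had received PBS or bleomycin, a DNA-damaging drug that injures the lung and leads to fibrosis. Each treatment was combined with a control gapmer, gapmer 1 or gapmer 3. A gapmer is a short antisense oligonucleotide that directs cleavage of its target RNA, and gapmers 1 and 3 target Dnm3os, a long noncoding RNA transcribed opposite to Dnm3. The PBS groups held 3 arrays each and the bleomycin groups 5 each. Deposited log2 intensities ran from 5.03 to 18.25, and 20728 named genes were tested. The number of arrays limits the precision. The labels number the samples within groups but name no animals, so the p-values measure the spread between these samples.

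Dnm3os itself was compared first, as a check of the labels. In bleomycin mice its brightest array feature lay at 6.90 ± 0.17 (SD, n = 5) with the control gapmer, 6.18 ± 0.19 with gapmer 1 and 6.40 ± 0.22 with gapmer 3. Dnm3os fell by 0.72 with gapmer 1 (SE 0.11, limma adjusted p = 0.000186) and by 0.50 with gapmer 3 (SE 0.11, limma adjusted p = 0.00293). All 5 gapmer 1 arrays and 4 of the 5 gapmer 3 arrays lay below the lowest control array. Two-sided exact permutation tests over all assignments of 5 against 5 gave p = 0.00794 for gapmer 1 and p = 0.0159 for gapmer 3, or 0.0238 and 0.0318 after adjustment over 6 such tests. In PBS mice the level was 6.34 ± 0.06 (SD, n = 3) with control, 5.89 ± 0.15 with gapmer 1 and 6.10 ± 0.14 with gapmer 3, and every gapmer array lay below every control array. Neither PBS difference passed (limma adjusted p = 0.0882 and 0.577; exact permutation p = 0.1 in both, the smallest that 3 against 3 arrays allow). A second feature differed by -0.28 with gapmer 1 (exact permutation p = 0.00794) and by -0.21 with gapmer 3 (exact permutation p = 0.0556) in bleomycin mice. The PBS levels with both gapmers lay under 6.11, the 25th percentile of gene means. So did the second feature with gapmer 1 in bleomycin mice (6.10), and the size of these differences is therefore not resolved. The remaining feature lay between 5.71 and 5.86 in all 6 groups, too dim to show a fall. The level of Dnm3os was at the 47.8th percentile of all features. Bleomycin itself raised Dnm3os by 0.56, so a weaker injury response would lower it too. The bleomycin comparisons alone therefore cannot tell this from cleavage by the gapmers. The gapmer 1 mean in bleomycin mice (6.18) lay below the PBS control mean (6.34), and the gapmer 3 mean (6.40) near it. Dnm3, on the other strand, differed by 0.52 with gapmer 1 in bleomycin mice, which did not pass (limma adjusted p = 0.0833). Without gapmer 1 bleomycin replicate 2 the difference was 0.29 (limma adjusted p = 0.234), and it passed with array weights (0.69) or without gapmer 1 bleomycin replicate 4 (0.62, limma adjusted p = 0.0353).

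**Figure D1:**
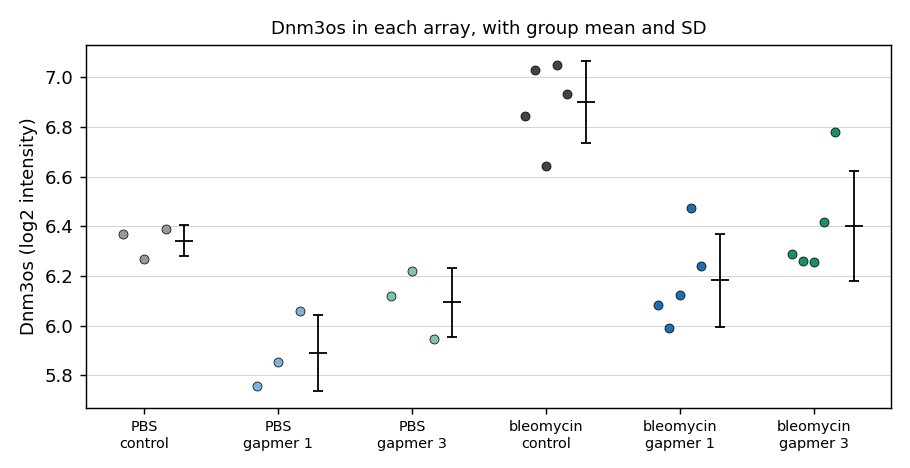
Dnm3os log2 intensity of every array (points) in the 6 groups, with the group mean and SD (bars). The control bleomycin mean of 6.90 lies above the gapmer 1 mean of 6.18 and the gapmer 3 mean of 6.40, and also above the PBS control mean of 6.34.

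Bleomycin was compared with PBS under the control gapmer to ask what the injury changed in the lung (n = 5 and 3). Matrix and scar genes rose strongly: Spp1, which encodes osteopontin, rose 14.6-fold (log2 3.87, SE 0.20), and Timp1, an inhibitor of matrix metalloproteinases, 12.4-fold (log2 3.63, SE 0.29). The collagen gene Col1a1 rose 3.64-fold, the fibronectin gene Fn1 2.93-fold, and the matrix gene Tnc by 2.26 on the log2 scale (SE 0.14). The largest rises included Clca1 at 4.81 (SE 0.67), the basal-cell keratin Krt5 at 4.44 (SE 0.90), the cornified-envelope gene Sprr2f at 4.38 (SE 0.21) and the acute-phase gene Saa3 at 4.27 (SE 0.40). The rises of Sprr2f and Tnc are lower bounds, since their PBS control levels of 5.64 and 5.91 lay under 6.11, the 25th percentile of gene means. Dnm3os itself rose by 0.56 (SE 0.12, limma adjusted p = 0.00112). Several of the largest falls were in muscle genes: Myh2 fell by 6.79 (SE 1.63), and Myl2, Pvalb, Ckmt2 and Tnnt1 fell as well. Myh2 stood at 12.91 (SD 1.04) in PBS controls, 8.76 (SD 2.21) and 9.03 (SD 4.18) with gapmers 1 and 3 in PBS mice and 6.12 (SD 0.13) in bleomycin controls. The skeletal muscle list score, its mean log2 difference from PBS controls, ran from -4.84 to 0.62 within the PBS gapmer 3 group. Within the bleomycin gapmer 3 group it ran from -3.83 to 0.76. Muscle signal thus varied strongly between samples of the same group. The fat-cell hormone gene Retn fell by 2.28 and Fabp1, a fatty acid-binding protein gene, by 3.28.

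Among the gene lists, 34 of 39 measured extracellular matrix genes rose and none fell (35 and 1 adjusted over the list alone), with the elastin gene Eln rising 12.3-fold beside Timp1. The fry test, which asks whether the genes of a list move on balance one way and does not compare them with other genes, gave adjusted p = 2.31e-08 for this list. Of 19 monocyte-derived macrophage genes, 16 rose and 1 fell (16 and 1 adjusted over the list alone, fry adjusted p = 2.69e-11), including Arg1 at 3.29, Trem2 at 3.15 and the elastase gene Mmp12 by at least 3.37, as its PBS control level of 6.09 lay under 6.11 too. Of 25 cytokine and chemokine genes, 19 rose, with the monocyte attractant Ccl2 at 3.06 and the neutrophil attractant Cxcl5 at 2.53, and 1 fell (20 and 1 adjusted over the list alone, fry adjusted p = 1.14e-09). In the p53 and DNA damage list 11 of 19 genes rose and 1 fell (12 and 2 adjusted over the list alone, fry adjusted p = 3.84e-09), including the cell cycle inhibitor Cdkn1a at 2.08. Damage-associated epithelial genes rose in 14 of 15 cases (14 adjusted over the list alone, fry adjusted p = 7.49e-09), among them the tight junction gene Cldn4 at 2.33. Of 25 markers of squamous epithelium, chosen after values were seen, 14 rose and 1 fell in the same comparison with a median of 0.73, and Krt13 stood at 9.06 in PBS controls and 12.90 in bleomycin controls. Endothelial genes fell in 15 of 17 cases (15 adjusted over the list alone, fry adjusted p = 7.49e-09), such as the receptor genes Ednrb (-1.35) and Kdr (-1.10). These 6 lists also passed the camera test with an estimated correlation, at adjusted p = 0.0351, 0.025, 0.025, 0.0261, 0.0261 and 0.0261.

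Another 19 lists passed fry but not camera with an estimated correlation. Proliferation genes rose in 18 of 21 cases (18 adjusted over the list alone), with Ccna2 at 2.46, Top2a at 2.22 and Mki67 at 2.09 (fry adjusted p = 4.17e-08; adjusted p = 0.0596 with an estimated correlation). T cell genes rose in 13 of 15 cases (13 adjusted over the list alone), including Cd5 at 1.45 and the regulatory T cell gene Foxp3 at 1.38 (fry adjusted p = 3.11e-07; adjusted p = 0.0641 with an estimated correlation). NK and cytotoxic genes fell in 9 of 12 cases and rose in 1 (9 and 1 adjusted over the list alone), with Gzma at -1.42 (fry adjusted p = 3e-04; adjusted p = 0.279 with an estimated correlation). Alveolar type 1 cell genes fell in 11 of 14 cases and rose in 2 (11 and 2 adjusted over the list alone), among them Cav1 at -0.94 and Hopx at -0.92 (fry adjusted p = 2.23e-05; adjusted p = 0.216 with an estimated correlation). Alveolar type 2 cell genes fell in 6 of 15 cases (6 adjusted over the list alone), including the surfactant gene Sftpa1 at -0.89 (fry adjusted p = 0.00208; adjusted p = 0.377 with an estimated correlation). Sftpc lay at 17.99 and 18.03 in PBS and bleomycin controls, close to the highest value on the arrays, so a change in it cannot be read. Resident fibroblast genes fell in 7 of 17 cases and rose in 2 (8 and 2 adjusted over the list alone), with Inmt at -1.82 (fry adjusted p = 0.00028; adjusted p = 0.279 with an estimated correlation). In the TGF-beta response 11 of 21 genes rose and 4 fell (11 and 4 adjusted over the list alone), with Inhba at 2.24 and Tgfb1 at 0.47 (fry adjusted p = 2.78e-05; adjusted p = 0.124 with an estimated correlation). In the contractile and myofibroblast list 4 of 14 rose, Acta2 by 0.89, and 1 fell (4 and 1 adjusted over the list alone, fry adjusted p = 0.0235; adjusted p = 0.437 with an estimated correlation). Wnt signalling genes rose in 11 of 23 cases and fell in 4 (11 and 6 adjusted over the list alone), with Wnt10a at 3.11 and Sfrp1 at 2.14 (fry adjusted p = 3.03e-06; adjusted p = 0.11 with an estimated correlation).

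The other 10 of these 19 lists covered further cell types, responses and tissues. Interferon response genes rose in 13 of 23 cases (14 with 1 fall adjusted over the list alone; fry adjusted p = 0.000746, and adjusted p = 0.279 with an estimated correlation). B and plasma cell genes rose in 4 of 11 cases (4 adjusted over the list alone; fry adjusted p = 0.0459, and adjusted p = 0.441 with an estimated correlation). Antioxidant genes rose in 6 of 13 cases and fell in 3 (7 and 4 adjusted over the list alone), with the haem-degrading enzyme gene Hmox1 at 1.35 (fry adjusted p = 0.0326; adjusted p = 0.472 with an estimated correlation). Of 13 described targets of the microRNAs that Dnm3os encodes, 7 fell and 2 rose (the same counts adjusted over the list alone; fry adjusted p = 1.58e-05, and adjusted p = 0.187 with an estimated correlation). Gsk3b and Ptgs2, members of that list, differed by -0.15 and 0.13 and did not pass. Mesothelial genes fell in 7 of 9 cases and rose in 2 (7 and 2 adjusted over the list alone), with Wt1 at -1.06 and the keratin Krt14 at 3.69 (fry adjusted p = 8.25e-08; adjusted p = 0.0882 with an estimated correlation). Clock genes fell in 9 of 15 cases and rose in 2 (11 and 3 adjusted over the list alone), with Dbp at -1.14 and Nfil3 at 1.15 (fry adjusted p = 1.2e-06; adjusted p = 0.0943 with an estimated correlation). The neutrophil list passed fry in the upward direction with a median of -0.18 and a mean of -0.02, as 3 of 11 genes rose and 3 fell (3 and 3 adjusted over the list alone; fry adjusted p = 0.0459, and adjusted p = 0.732 with an estimated correlation). Markers of other tissues moved with bleomycin too: red blood cell genes fell in 5 of 7 cases (5 adjusted over the list alone), with Hbb-b1 at -0.88 (fry adjusted p = 5.4e-05; adjusted p = 0.216 with an estimated correlation). Adipose genes fell in 6 of 9 cases (6 adjusted over the list alone; fry adjusted p = 0.00523, and adjusted p = 0.377 with an estimated correlation). Cardiac muscle genes fell in 6 of 12 cases (9 adjusted over the list alone; fry adjusted p = 0.00102, and adjusted p = 0.284 with an estimated correlation).

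In 6 lists fry found no shift on balance. Airway epithelial genes rose in 4 of 15 cases, Muc5ac by 1.5 and Ltf by 1.81, and fell in 7 (5 and 7 adjusted over the list alone), with a median of -0.28, a mean of 0.06 and fry adjusted p = 0.236. Alveolar macrophage genes rose in 4 of 12 cases and fell in 5 (5 and 5 adjusted over the list alone), with a median of -0.17, a mean of -0.47 and an upward fry adjusted p = 0.416. Skeletal muscle genes had a median of -1.08, with 2 of 11 lower (2 adjusted over the list alone, fry adjusted p = 0.116). Thymus genes rose in 1 and fell in 1 of 8 cases (1 and 1 adjusted over the list alone, fry adjusted p = 0.712). Immediate early genes rose in 3 of 13 cases and fell in 1 (3 and 1 adjusted over the list alone), with a median of -0.03, a mean of 0.11 and an upward fry adjusted p = 0.416. None of 6 sex-linked genes changed (0 adjusted over the list alone, fry adjusted p = 0.308, camera adjusted p = 0.598 with a preset and 0.673 with an estimated correlation).

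In limma, 7001 of 20728 genes changed with bleomycin at an adjusted p under 0.05, 3003 higher and 3998 lower. Of these, 592 were more than 2-fold higher and 291 more than 2-fold lower. The 95% interval of a gene had a median half-width of 0.21 on the log2 scale.

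**Figure D2:**
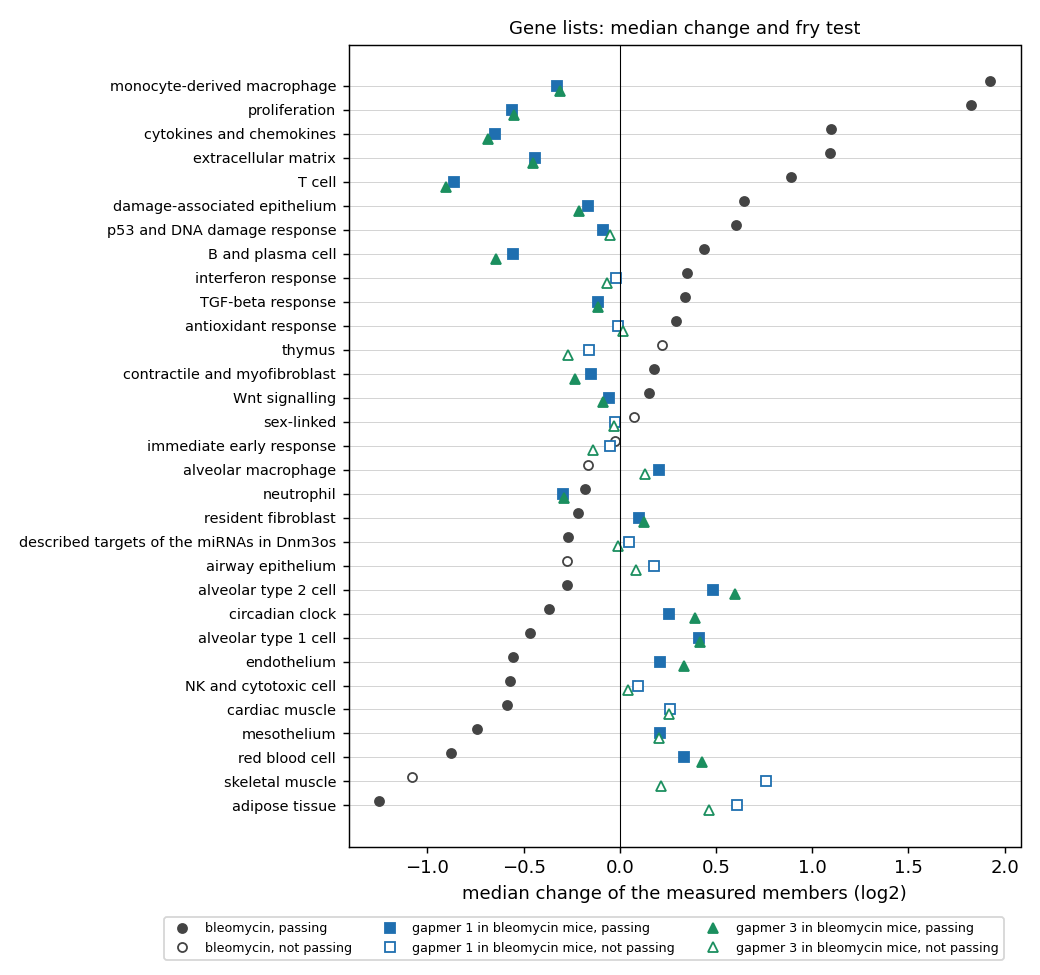
Median log2 change of the measured members of each gene list with bleomycin (circles), with gapmer 1 in bleomycin mice (squares) and with gapmer 3 in bleomycin mice (triangles). Filled symbols passed the fry test. The extracellular matrix median was 1.09 with bleomycin, -0.44 with gapmer 1 and -0.45 with gapmer 3.

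Gapmer 1 was compared with the control gapmer in bleomycin mice to ask what this oligonucleotide against Dnm3os changes in the injured lung (n = 5 and 5). Timp1 fell by 1.66 (SE 0.25), Tnc by 1.04 (SE 0.12) and Acta2, the smooth muscle actin of myofibroblasts, by 0.64 (SE 0.12). Fn1, Col1a1 and Spp1 fell by 0.57, 0.54 and 0.73, whereas Col3a1 differed by -0.35 and did not pass (limma adjusted p = 0.0932). The largest falls were in genes that bleomycin had induced: Sprr2f fell by 4.47 (SE 0.18), the protease inhibitor gene Spink8 by 3.73 (SE 0.12), and the matrix metalloproteinase gene Mmp7 (-3.54, SE 0.26), Glycam1 (-3.13, SE 0.22) and the keratin Krt17 (-2.98, SE 0.12) fell as well. With gapmer 1 Sprr2f, Spink8, Mmp7 and Glycam1 lay under 6.11, the 25th percentile of gene means, so their falls are lower bounds. Among the rises were the complement gene Hc at 0.76 (SE 0.15), Thbs3 at 0.79 (SE 0.15) and Fabp1 at 1.02 (SE 0.29). The muscle gene Myh2, which varied strongly between samples of some groups, rose by 4.72 (SE 1.41, limma adjusted p = 0.0339).

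Several inflammatory and lymphocyte groups were lower with gapmer 1. Of 25 cytokine and chemokine genes, 18 fell, including Cxcl5 by 2.19, Ccl2 by 1.45 and Il6 by 1.33, and 1 rose (21 and 1 adjusted over the list alone, fry adjusted p = 3.97e-06). T cell genes fell in 12 of 15 cases, with the receptor genes Cd6 at -1.08 and Cd3d at -0.95 (13 adjusted over the list alone, fry adjusted p = 3.29e-06). Both lists also passed with an estimated correlation (adjusted p = 0.0141 each). B and plasma cell genes fell in 8 of 11 cases (8 adjusted over the list alone), with the B cell antigen receptor gene Cd79a at -0.89 (fry adjusted p = 0.00107; adjusted p = 0.1 with an estimated correlation). Monocyte-derived macrophage genes fell in 7 of 19 cases (11 with 2 rises adjusted over the list alone), with Arg1 at -1.73 (fry adjusted p = 0.00788; adjusted p = 0.167 with an estimated correlation). Extracellular matrix genes fell in 17 of 39 cases and none rose (23 and 0 adjusted over the list alone; fry adjusted p = 0.00198, and adjusted p = 0.109 with an estimated correlation). Proliferation genes fell in 11 of 21 cases, Top2a by 0.83 (17 adjusted over the list alone; fry adjusted p = 0.00427, and adjusted p = 0.138 with an estimated correlation). TGF-beta response genes fell in 5 of 21 cases and rose in 1 (5 and 1 adjusted over the list alone, fry adjusted p = 0.0129). Contractile and myofibroblast genes fell in 4 of 14 (4 adjusted over the list alone, fry adjusted p = 0.00895). With an estimated correlation both had adjusted p = 0.167. Fry called 20 lists, including resident fibroblast (upward, adjusted p = 0.033) and neutrophil (downward, adjusted p = 0.0145), and camera with an estimated correlation 2. The NK and cytotoxic cell list did not pass, with 1 of 12 genes lower (1 higher and 1 lower adjusted over the list alone, fry adjusted p = 0.681), nor did the interferon response list, with 2 of 23 lower (2 adjusted over the list alone, fry adjusted p = 0.471).

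Genes of the alveolar surface moved the other way. Alveolar type 2 cell genes rose in 10 of 15 cases (11 adjusted over the list alone), with Sftpa1 at 0.62 and Lamp3 at 0.59 (fry adjusted p = 0.00019; adjusted p = 0.0928 with an estimated correlation). Alveolar type 1 cell genes rose in 9 of 14 cases (12 adjusted over the list alone), with Rtkn2 at 0.71, Clic5 at 0.60 and Hopx at 0.50 (fry adjusted p = 0.000128; adjusted p = 0.0928 with an estimated correlation). Endothelial genes rose in 3 of 17 cases (5 adjusted over the list alone), with Ednrb at 0.56 and Tek at 0.39 (fry adjusted p = 0.00106; adjusted p = 0.1 with an estimated correlation). Of the 13 described microRNA targets 2 rose and 1 fell (3 and 1 adjusted over the list alone; fry adjusted p = 0.201), and Cav1, one of them, differed by 0.36 and did not pass (limma adjusted p = 0.0529). Red blood cell genes rose in 2 of 7 cases (4 adjusted over the list alone; fry adjusted p = 0.0133, and adjusted p = 0.22 with an estimated correlation), Hbb-b1 by 0.49. Mesothelial genes rose in 3 of 9 cases (4 with 1 fall adjusted over the list alone; fry adjusted p = 0.00788, and adjusted p = 0.212 with an estimated correlation), with an upward median of 0.21 and a mean of -0.005. Skeletal muscle genes had a median of 0.76 with Myh2 alone passing (1 adjusted over the list alone, fry adjusted p = 0.418), and adipose genes a median of 0.61, a mean of 0.10 and none passing in limma (2 higher and 1 lower adjusted over the list alone, fry adjusted p = 0.479).

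In limma, 2186 genes changed with gapmer 1 in bleomycin mice, 1133 higher and 1053 lower. Of these, 6 were more than 2-fold higher and 82 more than 2-fold lower. The count depended on the arrays used: it was 1209 without control bleomycin replicate 2, 1440 without gapmer 1 bleomycin replicate 2, and 1278 when only these groups entered the fit, but 4231 with array weights.

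Gapmer 3 was compared with the same controls to ask whether another oligonucleotide against Dnm3os gives a similar change (n = 5 and 5). Timp1 fell by 1.93 (SE 0.25), Tnc by 1.11 (SE 0.12) and Acta2 by 0.79 (SE 0.12). Col1a1 and Fn1 fell by 0.45 and 0.50, while Col3a1 and Spp1 differed by -0.37 and -0.50 and did not pass (limma adjusted p = 0.0739 and 0.0615). Large falls were those of Sprr2f (-4.46, SE 0.18), Spink8 (-3.74, SE 0.12), Mmp7 (-3.40, SE 0.26), Krt17 (-3.13, SE 0.12), Clca1 (-3.10, SE 0.58) and Krt5 (-2.35, SE 0.78). That of Krt5 passed narrowly (limma adjusted p = 0.0489) and was -1.67 and did not pass without gapmer 3 bleomycin replicate 1 (limma adjusted p = 0.138). Those of Sprr2f, Spink8 and Mmp7 are lower bounds, because their levels with gapmer 3 lay under 6.11, the 25th percentile of gene means. Hc rose by 1.00 (SE 0.15), the amino acid transporter gene Slc7a10 by 1.27 (SE 0.27) and the methyltransferase gene Inmt by 0.79 (SE 0.22). Myh2 differed by 3.95 and did not pass (limma adjusted p = 0.0683).

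T cell genes fell in 12 of 15 cases (12 adjusted over the list alone, fry adjusted p = 4.85e-07), with Cd6 at -1.27 and Cd3d at -1.14. Cytokine and chemokine genes fell in 17 of 25 cases and rose in 1 (19 and 1 adjusted over the list alone, fry adjusted p = 4.85e-07), with Cxcl5 at -2.08, Il6 at -1.65, Ccl8 at -1.58 and Ccl2 at -1.45. Endothelial genes rose in 9 of 17 cases (13 adjusted over the list alone, fry adjusted p = 1.54e-05), with Ednrb at 0.52 and Tek at 0.46. Alveolar type 2 cell genes rose in 12 of 15 cases (14 adjusted over the list alone, fry adjusted p = 1.76e-05), Lamp3 by 0.64. With an estimated correlation these 4 lists had adjusted p = 0.02, 0.02, 0.029 and 0.0334. Alveolar type 1 cell genes rose in 9 of 14 cases (11 adjusted over the list alone), with Clic5 at 0.70 and Cav1 at 0.45 (fry adjusted p = 3.08e-05; adjusted p = 0.0522 with an estimated correlation). Extracellular matrix genes fell in 19 of 39 cases (26 adjusted over the list alone; fry adjusted p = 0.000978, and adjusted p = 0.119 with an estimated correlation). Damage-associated epithelial genes fell in 6 of 15 cases (11 adjusted over the list alone; fry adjusted p = 0.000218, and adjusted p = 0.0794 with an estimated correlation). Of the 25 squamous markers, chosen after values were seen, 5 fell as well and none rose, with a median of -0.38, and gapmer 3 replicate 1 stood apart as lowest for Krt5 (8.11), Krt14 (7.03), Krt13 (6.88) and Krt4 (5.95). B and plasma cell genes fell in 8 of 11 cases (8 adjusted over the list alone; fry adjusted p = 0.00017, and adjusted p = 0.0794 with an estimated correlation). Macrophage genes of the monocyte-derived list fell in 5 of 19 cases, Arg1 by 2.07, and 1 rose (10 and 2 adjusted over the list alone; fry adjusted p = 0.0201, and adjusted p = 0.311 with an estimated correlation). TGF-beta response genes fell in 5 of 21 cases and rose in 2 (6 and 2 adjusted over the list alone, fry adjusted p = 0.0185). Contractile and myofibroblast genes fell in 5 of 14 (5 adjusted over the list alone, fry adjusted p = 0.000453). With an estimated correlation they had adjusted p = 0.286 and 0.105. Fry called 17 lists, including resident fibroblast (upward, adjusted p = 0.00483) and neutrophil (downward, adjusted p = 0.00613). The microRNA target list did not pass (1 higher and 1 lower of 13, the same adjusted over the list alone, with a median of -0.01, a mean of 0.04 and an upward fry adjusted p = 0.484). Red blood cell genes rose in 3 of 7 cases (4 adjusted over the list alone; fry adjusted p = 0.00637, and adjusted p = 0.187 with an estimated correlation), Hbb-b1 by 0.60. Skeletal muscle genes had a median of 0.21 and none passed in limma (0 adjusted over the list alone, fry adjusted p = 0.621). Adipose genes had a median of 0.47 and a mean of -0.07, with 1 of 9 lower (0 adjusted over the list alone, fry adjusted p = 0.75).

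In limma, 2726 genes changed with gapmer 3 in bleomycin mice, 1167 higher and 1559 lower, with 5 more than 2-fold higher and 121 more than 2-fold lower. Without control bleomycin replicate 2 the count was 1775, and with array weights 5121.

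**Figure D3:**
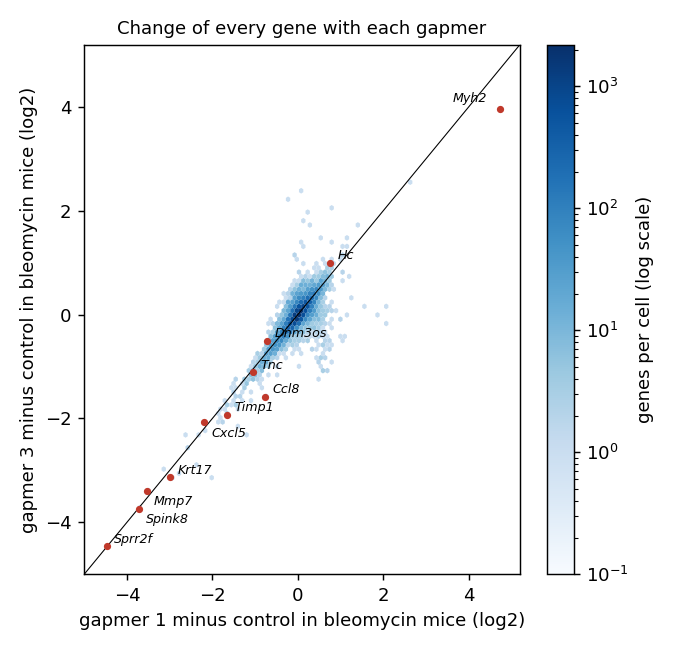
Log2 change of each of 20728 genes with gapmer 1 (horizontal axis) and gapmer 3 (vertical axis) in bleomycin mice, both against the same 5 control arrays. Shading gives the number of genes, the line marks equal change and named genes are red; the correlation across genes was 0.833.

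The changes with gapmers 1 and 3 were then set against each other. Across 20728 genes, which are not independent replicates, they correlated with r = 0.833 and a covariance of 0.052. Both comparisons use the same 5 control arrays, so 100 simulations of unchanged groups against shared controls were run and gave a mean r of 0.494 with a range from -0.105 to 0.846, which includes the observed r. The covariance in these simulations averaged 0.0111 and ranged from -0.00232 to 0.0279, and the observed one lay above all of them, by 0.0409 from the mean. In all, 780 genes were higher and 948 lower with both gapmers, and none moved in opposite directions. Independent lists would share 63.8 and 79.2 genes, and the simulated unchanged groups shared 0. With the 5 controls split into 2 for one gapmer and 3 for the other, the 20 splits gave a median r of 0.613, a median covariance of 0.0441, and a median of 160 genes shared upward and 388.5 downward. Direct comparison of gapmer 3 with gapmer 1 in bleomycin mice (n = 5 and 5) called 0 genes in limma, against 838 at an unadjusted p under 0.05, and 0 lists in fry (5 in camera with a preset and 0 with an estimated correlation). Among genes above the median level, the smallest p-values in each direction belonged to the chemokine gene Ccl8 (-0.82, SE 0.15), Ptprs (-0.25) and S100a6 (-0.26), all at limma adjusted p = 0.284, and to Mex3d (0.20), Kit (0.26) and Calcrl (0.30) at 0.992. The 95% interval of a gene in this comparison had a median half-width of 0.18 before adjustment, and on simulated data the same comparison recovered 81.2% of genes that differed 1.5-fold, so such differences can be missed.

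A small set of bleomycin-induced genes lost most of its rise with either gapmer. Bleomycin raised 122 genes more than 4-fold, and 10 of them had lost at least 75% of their log2 rise with both gapmers: Alox12e, Chil4, Cxcl5, Glycam1, Krt17, Mmp7, Spink8, Sprr2d, Sprr2f and Ubd, a set chosen after its values were seen. Spink8 stood at 5.73 in PBS controls, 9.40 in bleomycin controls, 5.67 with gapmer 1 and 5.66 with gapmer 3, and Mmp7 at 5.69, 9.21, 5.68 and 5.82. Spink8, Mmp7, Sprr2d and Sprr2f lay under 6.11, the 25th percentile of gene means, in PBS controls and with both gapmers, so their rises and falls are lower bounds and a return to the PBS level cannot be read from them. Glycam1 (5.89) and Krt17 (5.92) lay under it in PBS controls and Glycam1 (6.07) with gapmer 1, which makes these rises and that fall lower bounds too. In all 10 genes every bleomycin control array lay above all arrays of both bleomycin gapmer groups (n = 5 each). The genes were chosen for large differences between these same arrays, so this separation adds no independent evidence. As measured, with these bounds among the values, the median rise was 3.11 and the median changes were -2.77 with gapmer 1 and -2.95 with gapmer 3, against 0.13 with gapmer 1 in PBS mice.

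**Figure D4:**
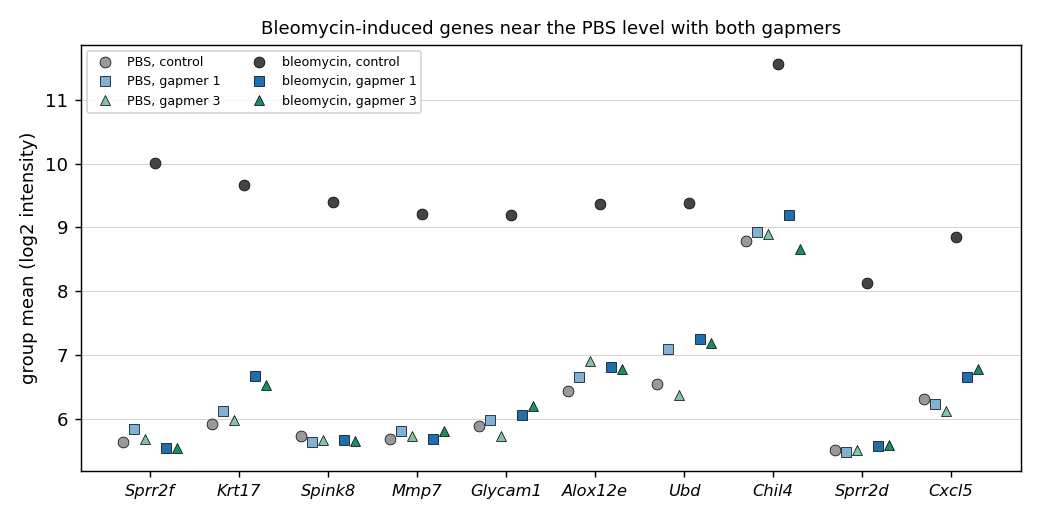
Group mean log2 intensity of the 10 genes in the 6 groups. In each gene the bleomycin control mean lies above both bleomycin gapmer means, as the choice of the genes required. Spink8 averages 9.40 in bleomycin controls and 5.67 and 5.66 with gapmers 1 and 3.

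Scores gave the matrix and bleomycin responses 1 value per sample. The extracellular matrix score, the mean log2 difference of 39 genes from PBS controls, was 1.21 ± 0.14 (SD, n = 5) in bleomycin controls, 0.77 ± 0.29 with gapmer 1 and 0.77 ± 0.13 with gapmer 3. Two-sided exact permutation tests over all assignments of 5 against 5 gave a difference of -0.44 with gapmer 1 (p = 0.0238; 0.0317 adjusted over 4 score tests) and of -0.45 with gapmer 3 (p = 0.00794, the smallest possible; 0.0159 adjusted). The score was below the lowest control in 4 of 5 gapmer 1 samples and 5 of 5 gapmer 3 samples, and 63.7% and 63.2% of the rise remained. Without the 4 arrays with the strongest position trend the gapmer 1 difference was -0.438 and did not pass (exact permutation p = 0.0571). That alternative was added after seeing the data and leaves fewer arrays. In PBS mice the score was 0.15 with gapmer 1 and -0.07 with gapmer 3 (exact permutation p = 0.1 and 0.3). The bleomycin-response score used genes chosen only in mice of the other gapmer. For gapmer 1, with 1454 raised and 1536 lowered genes, it was 0.98 ± 0.29 against 1.31 ± 0.14 in controls (n = 5 each). The difference of -0.33 did not pass (exact permutation p = 0.0714, also 0.0714 adjusted, with 4 of 5 samples below the lowest control). For gapmer 3, with 384 raised and 101 lowered genes, it was 1.5 ± 0.14 against 1.92 ± 0.12 (n = 5 each). The difference of -0.43 passed (exact permutation p = 0.00794, or 0.0159 adjusted, with 5 of 5 samples below the lowest control). This last call was lost without gapmer 1 PBS replicate 1 (-0.17, exact permutation p = 0.0714) or replicate 3 (-0.12, exact permutation p = 0.198), which change the genes chosen. The first one passed without gapmer 1 bleomycin replicate 4 (-0.43, exact permutation p = 0.0159), control bleomycin replicate 5 (-0.39, exact permutation p = 0.0397) or gapmer 3 PBS replicate 2 (-0.36, exact permutation p = 0.0317). Its p was also under 0.05 with RNA integrity as a covariate (-0.305, permutation p = 0.0476) or with the replicate block (-0.328, permutation p = 0.0238). Both p-values come from permuting scores already adjusted for the covariate or block, so they are approximate and not exact.

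**Figure D5:**
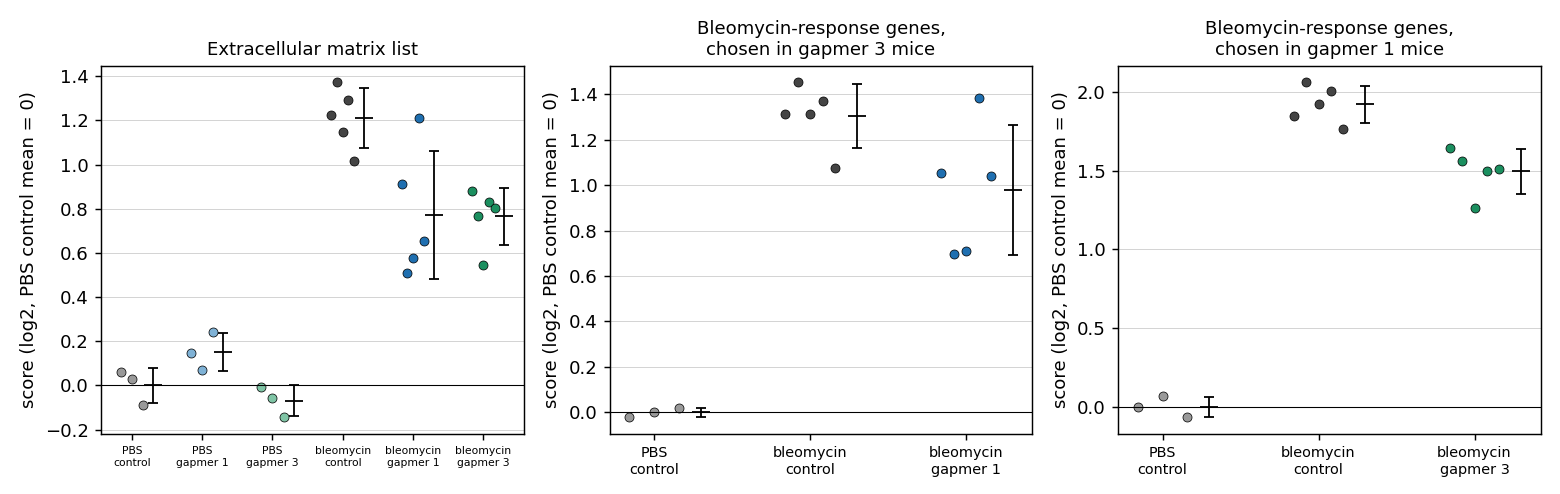
Scores of each sample (points) with group mean and SD (bars), on a log2 scale with the PBS control mean at 0. The left panel shows the extracellular matrix score in all 6 groups, and the others show the bleomycin-response scores for gapmer 1 and gapmer 3; the bleomycin control mean of the matrix score is 1.21 and both gapmer means are 0.77.

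The response to bleomycin under each gapmer was tested against that under the control gapmer, which asks whether the injury response itself differed. With gapmer 1 the rise of Timp1 was smaller by a log2 difference of -1.85 (SE 0.40), that of Tnc by -1.39 (SE 0.19) and that of Spp1 by -1.20 (SE 0.28), and those of Acta2, Col1a1, Col3a1 and Fn1 by -0.87, -0.79, -0.70 and -0.63. Col3a1 stood at 13.71 and 14.05 in PBS mice with control and gapmer 1, and at 15.26 and 14.90 in bleomycin mice. Its difference thus lay about equally in the PBS and the bleomycin groups. Sprr2f (-4.68, SE 0.30), Krt5 (-4.68, SE 1.27), Clca1 (-4.04, SE 0.95), Spink8 (-3.64, SE 0.19) and Arg1 (-2.74, SE 0.46) also responded less, with Sprr2f and Spink8 near the lowest levels of the arrays outside the bleomycin controls. Extracellular matrix genes responded less in 11 of 39 cases (16 adjusted over the list alone; fry adjusted p = 0.0127, and adjusted p = 0.177 with an estimated correlation). Monocyte-derived macrophage genes responded less in 10 of 19 cases (13 with 1 responding more adjusted over the list alone, fry adjusted p = 0.000262), Trem2 by -1.38, and T cell genes in 9 of 15 cases (13 adjusted over the list alone, fry adjusted p = 2e-04), Cd5 by -1.43. Trem2 stood at 9.96 and 11.14 in PBS mice with control and gapmer 1, and at 13.10 and 12.91 in bleomycin mice, so its difference lay mostly in the PBS groups. Cytokine and chemokine genes responded less in 12 of 25 cases and more in 1 (13 and 1 adjusted over the list alone, fry adjusted p = 0.000488). Damage-associated epithelial genes responded less in 5 of 15 cases (7 adjusted over the list alone, fry adjusted p = 0.000759). Of these, Krt5 and Sprr1a stood at 8.73 and 8.17 in PBS controls and at 12.19 and 10.81 in the PBS gapmer 1 group, where the squamous keratin Krt13 stood at 13.92 against 9.06 without passing. The difference was upward for 5 of 15 clock genes, 1.17 for Per1, and downward for 1 (10 and 1 adjusted over the list alone, fry adjusted p = 0.000189). Per1 stood at 13.77 and 13.65 in bleomycin mice with control and gapmer 1, and at 14.11 and 12.83 in PBS mice, so its difference lay in the PBS groups. The macrophage, T cell, cytokine, damage-associated and clock lists had adjusted p = 0.0484 with an estimated correlation. With gapmer 1 the macrophage list changed by a mean of 0.44 in PBS mice and -0.34 in bleomycin mice. The damage-associated list changed by 0.77 and -0.40, and the clock list by -0.31 and 0.13. The differences of these lists thus lay more in the PBS groups. Those of the T cell (0.08 and -0.74) and cytokine lists (0.06 and -0.65) lay mostly in the bleomycin groups. Of the 13 described microRNA targets 1 differed upward (3 adjusted over the list alone; fry adjusted p = 0.0279, and adjusted p = 0.347 with an estimated correlation). The adipose gene Retn (2.44, SE 0.63) and the muscle gene Myh2 (8.87, SE 2.30) also differed. Retn stood at 12.47 and 11.18 in PBS mice with control and gapmer 1, and at 10.18 and 11.35 in bleomycin mice. Myh2 stood at 12.91 (SD 1.04) in PBS controls and 8.76 (SD 2.21) in the PBS gapmer 1 group, and at 6.12 (SD 0.13) and 10.84 (SD 1.17) in bleomycin mice.

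Limma called 1597 genes for this difference, 1030 higher and 567 lower. The test includes the PBS groups of 3 arrays, and without PBS control replicate 1 or 3 the count was 802 or 857, without gapmer 1 PBS replicate 1 or 2 it was 882 or 859, without control bleomycin replicate 2 it was 969, and without gapmer 1 bleomycin replicate 4 it was 2574. Array weights called 3251.

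With gapmer 3 the response was also smaller for Timp1 (-1.76, SE 0.40), Tnc (-1.18, SE 0.19) and Acta2 (-1.08, SE 0.19), whereas Col1a1 (-0.29), Fn1 (-0.52), Spp1 (-0.62) and Col3a1 (-0.17) did not pass. Sprr2f (-4.51, SE 0.30), Clca1 (-3.90, SE 0.95) and Spink8 (-3.68, SE 0.19) responded less. T cell genes responded less in 9 of 15 cases (14 adjusted over the list alone; fry adjusted p = 0.000266, and adjusted p = 0.052 with an estimated correlation), and cytokine and chemokine genes in 6 of 25 with 1 responding more (12 and 1 adjusted over the list alone; fry adjusted p = 0.00165, and adjusted p = 0.0841 with an estimated correlation). Contractile genes responded less in 4 of 14 cases (6 adjusted over the list alone; fry adjusted p = 0.00732, and adjusted p = 0.131 with an estimated correlation). Extracellular matrix genes did so in 2 of 39 cases, and the list did not pass (4 adjusted over the list alone, fry adjusted p = 0.0882). Retn differed by 2.30 (SE 0.63, limma adjusted p = 0.0499). It stood at 12.47 and 10.87 in PBS mice with control and gapmer 3, and at 10.18 and 10.90 in bleomycin mice. Limma called 641 genes, 301 higher and 340 lower. The count ranged from 246 without PBS control replicate 1 to 1161 without control bleomycin replicate 5, 7 other arrays left out singly moved it by more than 1.5 times, and array weights called 1763.

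In PBS mice, gapmer 1 was compared with the control gapmer to ask what the oligonucleotide changed without injury (n = 3 and 3). Among the genes that rose most, the cornified-envelope gene Sprr1a rose by 2.64 (SE 0.60), the kallikrein gene Klk9 by 2.18 (SE 0.53), the aquaporin gene Aqp3 by 1.96 (SE 0.47) and the transglutaminase gene Tgm1 by 1.41 (SE 0.30). Of 25 markers of squamous epithelium, chosen after values were seen, 1 passed, with a median of 0.73 (MAD 1.03). The keratin Krt13, one of them, stood at 13.92 in this group against 9.06 in PBS controls, 10.34 in PBS gapmer 3 and 12.90 in bleomycin controls, and did not pass (limma adjusted p = 0.144). The clock gene Per1 fell by 1.28 (SE 0.19), Tsc22d3, a target of glucocorticoids, by 1.00 (SE 0.23) and the transcription factor genes Wt1 and Klf2 by 0.97 and 0.88. The macrophage genes Trem2 and Gpnmb rose by 1.19 and 0.97, and Cdkn1a by 0.93. Of 39 extracellular matrix genes Mmp2 rose by 0.71 and the others, Col1a1 (0.25) and Timp1 (0.19) among them, did not pass (2 higher adjusted over the list alone, fry adjusted p = 0.667). Clock genes fell in 2 of 15 cases (8 with 1 rise adjusted over the list alone, fry adjusted p = 0.00115), mesothelial genes in 1 of 9 (7 with 1 rise adjusted over the list alone, fry adjusted p = 0.00205). Monocyte-derived macrophage genes rose in 2 of 19 cases (9 adjusted over the list alone, fry adjusted p = 0.00659), and damage-associated epithelial genes in 2 of 15 (5 adjusted over the list alone, fry adjusted p = 0.0141). With an estimated correlation all 4 lists had adjusted p = 0.126. The mesothelial list had a median of -0.36 and a mean of -0.08.

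Limma called 230 genes in this comparison, 92 higher and 138 lower. The count rested on single arrays of the 6, falling to 10 and 11 without PBS control replicate 3 or 1 and to 49, 45 and 85 without gapmer 1 PBS replicate 1, 2 or 3, while it was 684 without PBS control replicate 2; it was 68 when only these 6 arrays were fitted and 732 with array weights.

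Gapmer 3 was likewise compared with control in PBS mice (n = 3 and 3). The defensin-related gene Spag11b rose by 1.51 (SE 0.14, limma adjusted p = 7.2e-06) and the zinc finger gene Plagl1 by 0.59 (SE 0.10), and the phosphatase gene Ptprs fell by 0.79 (SE 0.06, limma adjusted p = 3.98e-07) and the integrin-like gene Itgbl1 by 0.75 (SE 0.14). The other 3 genes called, Upk3a (-0.98), Ptger3 (-0.94) and Mogat2 (-0.64), lay outside the naming rule and were chosen after their values were seen. Matrix genes such as Col1a1 (-0.16) and Timp1 (-0.16) did not pass. Limma called 7 genes, 2 higher and 5 lower, against 2024 at an unadjusted p under 0.05. The count was 2 without PBS control replicate 3 or gapmer 3 PBS replicate 1, 3 without PBS control replicate 1 and 30 without PBS control replicate 2. No list passed fry, while camera called 6 lists with a preset and 0 with an estimated correlation. Adipose genes had the largest list shift apart from skeletal muscle genes (medians -1.05 and -1.42; fry adjusted p = 0.101 and 0.639), and 8 of 9 adipose genes were lower adjusted over the list alone.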

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

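Tests of a mislabelled pair and values with the position trend removed were chosen after the results were seen. In each bleomycin group of 5 arrays the highest or lowest value was compared with its neighbour by Dixon's ratio at 0.71, and 42 of 435 groups of values (9.7%) were beyond it, where chance marks about 1 in 20 groups. Gapmer 3 replicate 3 held 15 of these, gapmer 1 replicate 4 held 8 and gapmer 3 replicate 1 held 7.

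Bleomycin gapmer 3 replicate 3 lay apart from the other 4 arrays of its group, with the log2 level lowest for Tnc (6.72), Top2a (8.33), Ccl2 (9.00), Cd5 (9.40), Cd3d (9.60), Gzma (11.85), Wnt10a (7.61) and Ltf (11.18) and highest for Fabp1 (9.63) and Tsc22d3 (14.65). Its list scores were lowest for monocyte-derived macrophage (1.02), T cell (-0.11) and NK and cytotoxic cell genes (-0.77), and highest for antioxidant genes (0.54), and its bleomycin-response score with the genes used for gapmer 1 was lowest (0.83). Bleomycin gapmer 1 replicate 4 was highest for Clca1 (14), Chil4 (10.21), Muc5ac (9.06), Ltf (12.63) and the Wnt signalling score (0.26) and lowest for Gzma (11.39), Clic5 (14.56) and Lamp3 (15.10). Bleomycin gapmer 3 replicate 1 was lowest for the squamous genes Krt5 (8.11), Krt14 (7.03), Klk9 (6.98), Aqp3 (8.70), Krt4 (5.95), Krt13 (6.88) and Krtdap (6.34). Single values apart from their group were Dnm3 (8.46) in gapmer 1 replicate 2, Hbb-b1 (16.62) and the red blood cell score (-0.72) in gapmer 1 replicate 1, Aqp3 (10.45) and Lef1 (10.29) in gapmer 1 replicate 3, and Tgfb1 (9.96) and Plagl1 (12.51) in gapmer 1 replicate 5. Further ones were Krt14 (7.35) and Cidec (11.10) in control replicate 5, S100a6 (16.52) and the thymus score (1.5) in control replicate 3, and the immediate early score (0.29) in gapmer 3 replicate 4.

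The bleomycin response was tested for a difference from that under the control gapmer. Limma called 1597 genes and fry 12 lists with gapmer 1, and 641 genes and 8 lists with gapmer 3. Camera with an estimated correlation called 5 and 0 lists. With gapmer 1 the log2 differences were -4.68 for Sprr2f, -4.68 for Krt5, -4.04 for Clca1, -3.64 for Spink8, -2.74 for Arg1, -1.85 for Timp1, -1.43 for Cd5, -1.39 for Tnc, -1.38 for Trem2, -1.20 for Spp1, -0.87 for Acta2, -0.79 for Col1a1, -0.70 for Col3a1 and -0.63 for Fn1, and 8.87 for Myh2, 2.44 for Retn and 1.17 for Per1. With gapmer 3 they were -4.51 for Sprr2f, -3.90 for Clca1, -3.68 for Spink8, -1.76 for Timp1, -1.18 for Tnc, -1.08 for Acta2 and 2.30 for Retn. Sprr2f and Spink8 lay under 6.11, the 25th percentile of gene means, in the PBS groups and with both gapmers, so the size of their differences is not resolved. Tnc lay under it in PBS mice with control and gapmer 3 (5.91 and 5.97), which leaves the size of its differences open as well. With gapmer 1 those of Per1 and Trem2 lay almost wholly in the PBS groups (Trem2 9.96 with control and 11.14 with gapmer 1, against 13.10 and 12.91 in bleomycin mice). That of Krt5 lay mostly there (8.73 and 12.19, against 13.18 and 11.96), and that of Clca1 about equally in both (8.40 and 10.40, against 13.21 and 11.17). Those of Col3a1 (13.71 and 14.05, against 15.26 and 14.90) and Retn (12.47 and 11.18, against 10.18 and 11.35) also lay about equally in both. With gapmer 3 that of Retn lay mostly in the PBS groups (12.47 and 10.87, against 10.18 and 10.90).

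Among array features without a gene name, which the comparisons above do not use, limma called 3393 with bleomycin, 703 with gapmer 1 and 1017 with gapmer 3 in bleomycin mice, and 67 with gapmer 1 in PBS mice. The bleomycin response differed in 509 of them with gapmer 1 and 204 with gapmer 3.

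Other splits of the same arrays were counted for every comparison. As many genes as the real split, itself included, were called by 1 of 56 splits for bleomycin (7001 genes, highest other 3418). The share was 1 of 100 for gapmer 3 in bleomycin mice (2726, highest other 200). It was also 1 of 100 for the response with gapmer 1 (1597, highest other 562) and with gapmer 3 (641, highest other 4). Chance is thus unlikely to give these counts, though such shares cannot exclude it. For gapmer 1 in bleomycin mice it was 2 of 100 (2186, highest other 3453), which makes chance unlikely too. A split that calls more genes than the real one, however, points to a structure of the samples. For the PBS comparisons the 10 splits are too few for a share under 0.05 (230 genes with gapmer 1 and 7 with gapmer 3, highest other 0 in both). Between gapmer 3 and gapmer 1 in bleomycin mice 100 of 100 splits called as many as the real 0 genes, with a highest other of 14, which any split would do, so this count says nothing about chance (838 genes had an unadjusted p under 0.05, and limma was the only tool run).

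The split with 3453 genes exchanged control replicate 5 and gapmer 1 replicate 4 of the bleomycin mice, and 1579 of its genes were among the 2186 of the real split. A mislabelled pair would put control replicate 5 among the gapmer arrays, but it lay closer to the other controls for 86.4% (19 of 22) of the genes that separate gapmer 3 from control replicates 1 to 4 by over 4-fold, which argues against an exchange. Gapmer 1 replicate 4 lay closer to the controls for 6 of them, against at most 1 for any other gapmer 1 array. A dim patch on control replicate 5 is argued against as the whole cause. With the position trend removed, the exchanged labels still called 3410 genes and the real ones 2749. Before removal they called 3453 and 2186, so the excess shrank and the patch may account for part of it. Beside that part, a weaker effect of gapmer 1 in replicate 4 stays open, for which no biological explanation was tested.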

How the results depend on the processing

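The position-trend alternatives (trend removed, and the 4 arrays with the strongest trend left out) were chosen after seeing the data. Of 26 main results, the changes of Dnm3os, the score differences and the agreement kept their sign under every alternative that gave them. Counts of genes and lists have no sign, and their balance of higher and lower did shift. With gapmer 1 in bleomycin mice it went from 1133 higher and 1053 lower to 1542 and 1778 with every feature tested. With gapmer 1 in PBS mice it went from 92 and 138 to 60 and 8 with only the groups compared. For the response with gapmer 3 it went from 301 and 340 to 1044 and 719 with array weights. Apart from the values given here, the main results stayed on their side of the threshold or within 1.5 times their count. The cause of the changes was not tested unless the alternative shows it. Testing every feature, which adds unnamed ones, called 12563 with bleomycin, 3320 with gapmer 1 and 4387 with gapmer 3 in bleomycin mice. Array weights called 4231 genes with gapmer 1 and 5121 with gapmer 3 in bleomycin mice, 732 with gapmer 1 in PBS mice, and 3251 and 1763 for the response with gapmer 1 and gapmer 3. Fitting only the groups compared, with fewer arrays, called 1278 with gapmer 1 in bleomycin mice, 68 with gapmer 1 and 1 with gapmer 3 in PBS mice. RNA integrity as a covariate called 424 and 4 genes with gapmers 1 and 3 in PBS mice and 287 for the response with gapmer 3. Adjusted for it, the bleomycin-response score with gapmer 1 differed by -0.305 (permutation p = 0.0476, approximate after that adjustment). Leaving out dim genes called 2 with gapmer 3 in PBS mice and gives no value for Dnm3os, which it removes. Trend removal called 968 genes for the response with gapmer 3. Without the 4 arrays it was 1314, with 689 for gapmer 1 in PBS mice, and the matrix score with gapmer 1 differed by -0.438 and no longer passed (exact permutation p = 0.0571), with fewer arrays. With the controls split between the gapmers the agreement was r = 0.613. Camera with an estimated correlation called 6 lists with bleomycin, 2 with gapmer 1 and 4 with gapmer 3 in bleomycin mice, 0 with gapmer 1 in PBS mice, and 5 and 0 for the responses with gapmers 1 and 3. With a preset correlation it called 8 and 6 lists with gapmers 1 and 3 in PBS mice, 19 for the response with gapmer 3 and 5 between the gapmers.

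Whether replicate numbers pair the samples stays open. Arrays of the same number in other groups had a mean residual correlation of 0.077 (51 pairs), against -0.02 for other pairs (186). The correlation was over 0.1 in 27 of the 51 and in 58 of the 186, and 7 of 24 arrays were closest to their own number. With the replicate block 423 genes were called with gapmer 1 in PBS mice and 1115 for the response with gapmer 3. Adjusted for the block, the bleomycin-response score with gapmer 1 differed by -0.328 (permutation p = 0.0238, approximate after that adjustment).

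With each of the 24 arrays left out in turn, genes called ranged from 5695 to 7339 with bleomycin, 1209 to 3092 with gapmer 1 and 1775 to 3065 with gapmer 3 in bleomycin mice, 10 to 684 and 2 to 30 with gapmers 1 and 3 in PBS mice, 802 to 2574 and 246 to 1161 for the responses, and stayed at 0 between the gapmers. The change of Dnm3os ranged from -0.79 to -0.669 and -0.594 to -0.461 with gapmers 1 and 3 in bleomycin mice, -0.538 to -0.388 and -0.31 to -0.173 in PBS mice, and 0.519 to 0.621 with bleomycin. Lists called ranged from 21 to 25 with bleomycin, 17 to 22 and 15 to 19 with gapmers 1 and 3 in bleomycin mice, 3 to 4 and 0 to 1 in PBS mice, 9 to 17 and 6 to 15 for the responses and 0 to 1 between the gapmers. The matrix score difference ranged from -0.549 to -0.373 with gapmer 1 and -0.494 to -0.391 with gapmer 3, the bleomycin-response score from -0.431 to -0.258 and -0.531 to -0.119, and the agreement from 0.788 to 0.865.

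The arrays whose absence moved a count over 1.5 times or changed a call were, for gapmer 1 in bleomycin mice, control replicate 2 (1209) and gapmer 1 replicate 2 (1440), and for gapmer 3 control replicate 2 (1775). For gapmer 1 in PBS mice they were PBS control replicates 1 (11), 2 (684) and 3 (10), PBS gapmer 1 replicates 1 (49), 2 (45) and 3 (85), PBS gapmer 3 replicate 1 (547), and of the bleomycin mice control replicate 4 (138), gapmer 1 replicate 5 (375) and gapmer 3 replicates 1 (372) and 5 (146), which enter only through the shared spread. For gapmer 3 in PBS mice they were PBS control replicates 1 (3), 2 (30) and 3 (2) and PBS gapmer 3 replicate 1 (2). For the response with gapmer 1 they were PBS control replicates 1 (802) and 3 (857), PBS gapmer 1 replicates 1 (882) and 2 (859), bleomycin control replicate 2 (969) and bleomycin gapmer 1 replicate 4 (2574). For that with gapmer 3 they were PBS control replicates 1 (246) and 3 (302), PBS gapmer 3 replicates 1 (278) and 2 (391), bleomycin control replicates 1 (424), 2 (312), 4 (359) and 5 (1161) and bleomycin gapmer 1 replicate 4 (1043). Lists called moved without PBS control replicate 1 (1 with gapmer 3 in PBS mice), bleomycin gapmer 1 replicates 3 (13) and 4 (15, both for the response with gapmer 3) and bleomycin gapmer 3 replicate 3 (1 between the gapmers). The bleomycin-response score with gapmer 1 passed without control replicate 5 (-0.385), gapmer 1 replicate 4 (-0.431) or PBS gapmer 3 replicate 2 (-0.359), and that with gapmer 3 did not pass without PBS gapmer 1 replicate 1 (-0.173) or 3 (-0.119).

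For the genes and lists named by rule, a result that passed in neither fit was counted as kept, whatever its sign. The alternatives set at the start, other than leaving out arrays, kept the call status in 4423 higher and 5734 lower values. They lost the call in 197 and 187, and gained it in 65 and 78. The added alternatives kept 894 and 1149, lost 38 and 49 and gained 14 and 16. Leaving out single arrays kept 10634 and 13782, lost 630 and 698 and gained 88 and 88. None reversed.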

Other observations

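Tests of one uniformly weaker response, of RNA integrity and of the time of day, and the position trend removed, were chosen after the results were seen. Of 122 genes raised more than 4-fold by bleomycin, the median gene kept 70.3% of its log2 rise with gapmer 1 and 63% with gapmer 3. On the linear scale, the median of 592 genes raised over 2-fold kept 54% of its rise with gapmer 1 and 50.5% with gapmer 3. Wnt signalling genes fell in 7 of 23 cases with either gapmer in bleomycin mice and rose in 2 (9 and 10 falls adjusted over the list alone; fry adjusted p = 0.00107 with gapmer 1 and 6.67e-05 with gapmer 3; adjusted p = 0.097 and 0.0667 with an estimated correlation), with Wnt10a at -0.94 and -1.32 and Sfrp1 at -0.95 and -1.10. Clock genes, which had mostly fallen with bleomycin, rose in 4 and 5 of 15 cases and fell in 2 with either (6 and 9 rises adjusted over the list alone; fry adjusted p = 0.0134 and 0.000453; adjusted p = 0.258 and 0.0827 with an estimated correlation), with Dbp at 0.51 and 0.59.

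The 10 bleomycin-induced genes that lost most of their rise with both gapmers were weighed against technical explanations. Squamous tissue carried into the bleomycin control samples would lower the squamous markers with both gapmers, but of 25 markers (chosen after values were seen, 0 on another list) the median change was 0.20 with gapmer 1 and -0.38 with gapmer 3, and the abundant Krt13 stood at 12.90 in bleomycin controls and 13.39 and 12.04 with gapmers 1 and 3. The markers that passed were all lower (3 with gapmer 1 and 5 with gapmer 3), and the dim Krt6a fell like the 10 genes (-1.28 and -1.32). The same retained share for every gene is argued against, as 31.8% and 32.8% of 592 genes raised over 2-fold lay outside its interval. They lay on both sides of it (17.9% below and 13.9% above with gapmer 1, 21.1% and 11.7% with gapmer 3). A weaker injury response that differs between genes is not addressed by this test. A position trend is argued against by the 99.8% of the median fall kept once it was removed. Whether these genes depend more on Dnm3os than the rest of the response, or respond to both oligonucleotides by another way, was not tested.

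The 230 genes called with gapmer 1 in PBS mice were weighed in the same way. Lower RNA integrity is argued against as the whole cause, since 99.6% (229 of 230) kept their call in the same direction with it as a covariate. Squamous tissue carried into these samples may account for part of the rises: in the 18 arrays of the other 4 groups, 91 risen genes correlated with the squamous score with a median of 0.28, with 37 above 0.5 and 37 under 0.2, against -0.1 for all bright genes, while of 25 squamous markers 1 passed, with a median of 0.73 (MAD 1.03), and Krt13, Krt4 and Sprr3, which did not pass (limma adjusted p = 0.144, 0.134 and 0.0998), stood at 13.92, 12.31 and 11.61 in this group and 9.06, 8.28 and 7.60 in PBS controls. A different time of day at collection cannot be told apart from the gapmer, because 11 of 15 clock genes had the sign of one phase shift (9 of 10 that it would lower, but 2 of 5 that it would raise), with Per1 and Per2 alone passing in limma, and collection times are not given in the sources used here. An effect of the oligonucleotide itself stays open beside these.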
